A study of Homo sapiens with 8 samples.

How the data were processed

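Gene expression was measured by RNA sequencing in human dermal microvascular endothelial cells, the cells that line small blood vessels of the skin, grown as primary cultures. The series holds 8 libraries in 4 groups of 2, and each group was named from the treatment in the labels. In 1 experiment cells carrying a short hairpin RNA against septin 2 (shSEPT2), incubated for 3 to 4 days per the labels' protocols, were set against cells with a control hairpin (shControl). In the other, cells labelled as given 20 ng/ml of tumour necrosis factor alpha (TNF) overnight were set against untreated cells. RNA was made into poly(A) libraries, per the labels' protocols.

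The authors deposited 2 tables of raw read counts per gene, 1 for each experiment, with a column per library. The submitters' processing notes name bcl2fastq, STAR 2.5.1a, Subread with featureCounts 1.4.6-p5 and Salmon 0.8.2, with no roles or order. The genome build, the annotation and the strand setting of the counting are not given in the sources used here, so reads of overlapping, antisense and near-identical genes may have been shared between them. Each deposited table held 34343 rows of counts for 34213 Ensembl genes, and the 130 rows that repeated a gene with the same counts were dropped. The tables had turned 27 gene symbols, septins among them, into dates, so symbols were looked up by Ensembl ID, which matched for 33972 IDs. A poly(A) count table reads the amount of each transcript relative to the rest of the library, so a change that scales every gene alike cannot be seen. Library totals lay between 42740490 and 46699845 counts, at which 3 counts correspond to 0.064 to 0.07 CPM, the usual scaling of counts to a common library total.

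Counts were analysed with R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0 and limma 3.58.1. The planned test of each comparison, fixed before the data were examined, was edgeR's quasi-likelihood F test with robust estimation. It was fitted to the 4 libraries of that comparison with TMM scaling and the default low-count filter (minimum count 10, minimum total count 15). Benjamini-Hochberg adjustment ran over all tested genes, and a gene was called at an adjusted p under 0.05. CPM values in the text are TMM-normalised and are given per library or as mean ± SD with n = 2, and single-gene ratios within a pair were taken after adding 0.05 CPM. Pair medians of lists, and the shares of genes that differed by over 2-fold, used edgeR log2 CPM with a prior count of 2.

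The planned edgeR test called 0 genes in either comparison. In all, 8 fits per comparison were then set side by side: edgeR as planned, with the replicate block and with RLE scaling, DESeq2 and limma-voom each with and without the block, and edgeR over all 8 libraries. Of these, DESeq2 and limma-voom with the block were added after seeing the data. DESeq2 without the block had been fixed as an alternative before, but the decision to name genes from it was taken after the planned test had called none and after the counts of all 8 fits had been seen. In what follows "rose" and "fell" of a gene in the septin 2 comparison refer to DESeq2 calls at an adjusted p under 0.05, none of which passed the planned edgeR test.

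The naming rule was fixed before the data were examined. It takes the targeted gene first, then the 12 highest and 12 lowest log2 fold changes among called protein-coding genes with a mean of at least 5 CPM that moved the same way in both pairs. It also takes up to 4 called members of each of 26 gene lists, and any septin. XIST and Y-linked genes were never named. List members were counted among genes that passed the low-count filter, and counting them by DESeq2 was also chosen after seeing the data. Lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, and camera with an estimated correlation and fry were alternatives.

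Replicate numbers go with a shared day in the labels, so same-numbered libraries were taken as pairs. Deviations of same-numbered libraries from their group means correlated across genes at 0.62 in the septin 2 experiment and 0.48 in the TNF experiment. Nothing in the labels says that the replicates came from separate donors, so p-values may measure only technical spread between cultures of the same cells. No libraries agreed within sampling noise: the lowest chi-square per gene between libraries, over genes with at least 20 reads in the pair, was 9.003, between untreated replicate 2 and TNF replicate 2.

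The fits were tested on 1 simulated data set per comparison, with the day effects, library sizes and blocked dispersions of the real libraries and 200 changed genes. For the septin 2 comparison (13916 genes), the planned edgeR test recovered 0% of genes changed by 1 on the log2 scale and 0% of those changed by 2. DESeq2 without the block recovered 4% and 73%, with 2 unchanged genes among 79 calls. With the block DESeq2 recovered 36% and 94%, and 15.3% of its calls were unchanged genes. EdgeR and limma-voom with the block recovered 95% and 96% of the genes changed by 2, with 20.8% and 21.7% of their calls unchanged genes. For the TNF comparison (14045 genes) the planned edgeR test recovered 62% of genes changed by 1 and 95% of those changed by 2, with 0 unchanged genes called. A mitotic list lowered by 1 was called by camera at the preset correlation in both simulations, and was missed with an estimated correlation (adjusted p = 0.997 for septin 2 and 0.727 for TNF). Simulated genes were independent, so the preset correlation itself was not tested. No simulated library carried a gene programme of its own beyond the day effects. The shares of unchanged genes among the calls may therefore not hold for the real libraries.

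Alternatives were another scaling, 2 other low-count filters, the replicate block, leaving out each library in turn, other tools, a fold threshold and protein-coding genes alone. Where 1 library was left out, the lone library of its group was assumed to vary like the other group. A call lost in such a fit therefore does not by itself show that the difference sat in 1 library. The planned sets of genes raised or lowered by TNF, called at an absolute log2 fold change of at least 1, had no members.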

Results

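RNA of human dermal microvascular endothelial cells was counted in 8 libraries: 2 with a control hairpin, 2 with a hairpin against septin 2, 2 untreated and 2 labelled as given TNF, an inflammatory cytokine. Totals were 46699845 and 43854182 counts for shControl replicates 1 and 2, and 44926374 and 42740490 for shSEPT2. They were 43333326 and 43579262 for untreated cells and 46216955 and 46295912 for the libraries labelled TNF. Mitochondrial transcripts took between 2.41% and 4.01% of the counts.

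The first comparison asked what the suppression of septin 2, a filament-forming GTPase of the cell cortex, does to the transcripts of endothelial cells. SEPTIN2 (ENSG00000168385) lies on the plus strand of chromosome 2, at 241315100 to 241354027 in GRCh38 (GENCODE release 29, used here for its position alone). It stood at 491.8 and 493.3 CPM in the shControl libraries and at 13.5 and 19.0 CPM in the shSEPT2 libraries. Those are 36.2-fold and 25.9-fold reductions within the same-numbered pairs (DESeq2 log2 fold change -4.92 ± 0.34 SE, adjusted p = 2.83e-44). The planned edgeR test gave the same log2 fold change with an adjusted p of 0.358. Of the 10 septin genes tested, SEPTIN9 also fell, from 318.5 ± 28.6 to 164.6 ± 14.2 CPM (SD, n = 2). Its DESeq2 log2 fold change was -0.95 (adjusted p = 0.0307). That call was lost whichever of the 4 libraries was left out, with log2 fold changes of -1.04 to -0.86. SEPTIN7, which assembles with septin 2, was at 122.0 and 94.7 CPM in shControl and at 111.8 and 94.4 CPM in shSEPT2. SEPTIN11 had a log2 fold change of 0.52 and SEPTIN6 of -0.81, and neither was called. Of 17 septin-binding and cytokinesis genes 0 rose and 1 fell (6 fell over the list alone, 7 with the block). This was KIF20A, at -2.96 (adjusted p 0.0261), and its call was lost without shControl replicate 1 and without either shSEPT2 library (adjusted p 0.526, 0.216 and 0.212).

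In the shSEPT2 libraries 2 of 18 adherens junction genes and 3 of 27 blood endothelial genes rose, and 0 of either fell (3 and 4 rose when adjusted over the list alone, 4 and 7 with the replicate block, when 2 of the blood endothelial genes also fell). Of 20 tight junction genes 0 rose and 1 fell, PARD6G (0 and 3 over the list alone, 3 and 2 with the block), and its adjusted p was 0.991 without shControl replicate 2, 0.274 without shSEPT2 replicate 1 and 0.214 with the block. Of 17 gap junction and Notch genes 0 rose and 1 fell, EFNB2 (0 and 3 over the list alone, 0 and 4 with the block). Of 16 leukocyte adhesion genes 1 rose, ICAM1, and 1 fell, CD99L2 (the same counts over the list alone, 6 and 1 with the block). The call of CD99L2 was lost without shControl replicate 2 (adjusted p = 0.0523), shSEPT2 replicate 1 (0.301) and shSEPT2 replicate 2 (0.178). ICAM1, the leukocyte adhesion receptor, went from 35.1 ± 8.88 to 236.0 ± 45.6 CPM (SD, n = 2), a DESeq2 log2 fold change of 2.75 ± 0.38 (adjusted p = 7.35e-10). CDH5, the VE-cadherin of endothelial adherens junctions, went from 1356.0 ± 41.5 to 3023.9 ± 47.1 CPM (log2 fold change 1.16 ± 0.26, adjusted p = 0.000784). Its partner phosphatase PTPRB rose by a log2 fold change of 1.19. Both calls were lost whichever library was left out, while the log2 fold change stayed at 1.14 to 1.18 for CDH5 and 1.1 to 1.27 for PTPRB. APLN, the ligand of the apelin receptor, rose 14.1-fold and 9.51-fold within the pairs, and FLT1, a receptor of VEGF, 8.07-fold and 4.12-fold. The call of FLT1 was lost without shSEPT2 replicate 1 (adjusted p = 0.244).

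The p53 target list rose as a group and the mitotic and DNA replication lists fell, by camera at the preset correlation (adjusted p = 0.743, 0.743 and 0.773 with an estimated correlation). Of 20 tested p53 targets 8 rose and 0 fell by DESeq2 (14 rose when adjusted over the list alone, and 15 with the replicate block over all genes). The cell cycle inhibitor CDKN1A went from 389.1 ± 5.04 to 1264.6 ± 96.7 CPM (SD, n = 2; log2 fold change 1.71 ± 0.27, adjusted p = 1.71e-07). FAS, TNFRSF10B and MDM2, the ubiquitin ligase of p53, rose with log2 fold changes of 1.95, 1.65 and 1.64. These 4 calls were lost without either shSEPT2 library, and that of FAS also without shControl replicate 2. Without 1 library the log2 fold change was 1.62 to 1.78 for CDKN1A and 1.46 to 2.65 for FAS. For TNFRSF10B it was 1.53 to 1.75 and for MDM2 1.41 to 1.83. Of 27 mitotic genes 12 fell and 0 rose (26 fell when adjusted over the list alone, and 26 with the block over all genes), among them CDC20, UBE2C, NUF2 and CCNB2 with log2 fold changes of -3.44, -3.23, -3.09 and -3.06. Of 25 DNA replication genes 4 fell and 0 rose (15 fell when adjusted over the list alone, and 12 with the block over all genes): UHRF1, TK1, RRM2 and POLE2, at -3.19, -2.92, -2.80 and -2.60. RRM2 had an adjusted p of 0.367 with the block.

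The size of the cell cycle difference depended on shControl replicate 1, in which CDC20 stood at 103.5 CPM against 14.3 CPM in shControl replicate 2, 7.24 CPM in shSEPT2 replicate 1 and 3.56 CPM in shSEPT2 replicate 2. The median log2 fold change of the mitotic list was -3.30 in pair 1 and -1.12 in pair 2, and that of the DNA replication list -2.44 and -0.50. Without shControl replicate 1, 0 mitotic genes were called by DESeq2, and 27 without shControl replicate 2. Without shSEPT2 replicate 1, 1 was called, and 0 without shSEPT2 replicate 2. For the DNA replication list these counts were 0, 18, 1 and 0, and for the p53 list 7, 6, 0 and 0. Without shControl replicate 1 the medians were -0.81 for the mitotic list and -0.52 for the DNA replication list. The p53 medians were 1.05 in pair 1 and 0.93 in pair 2. COL1A2, a fibroblast collagen gene, was also highest in shControl replicate 1 (162.8 CPM against 6.40 CPM in shControl replicate 2).

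**Figure D1:**
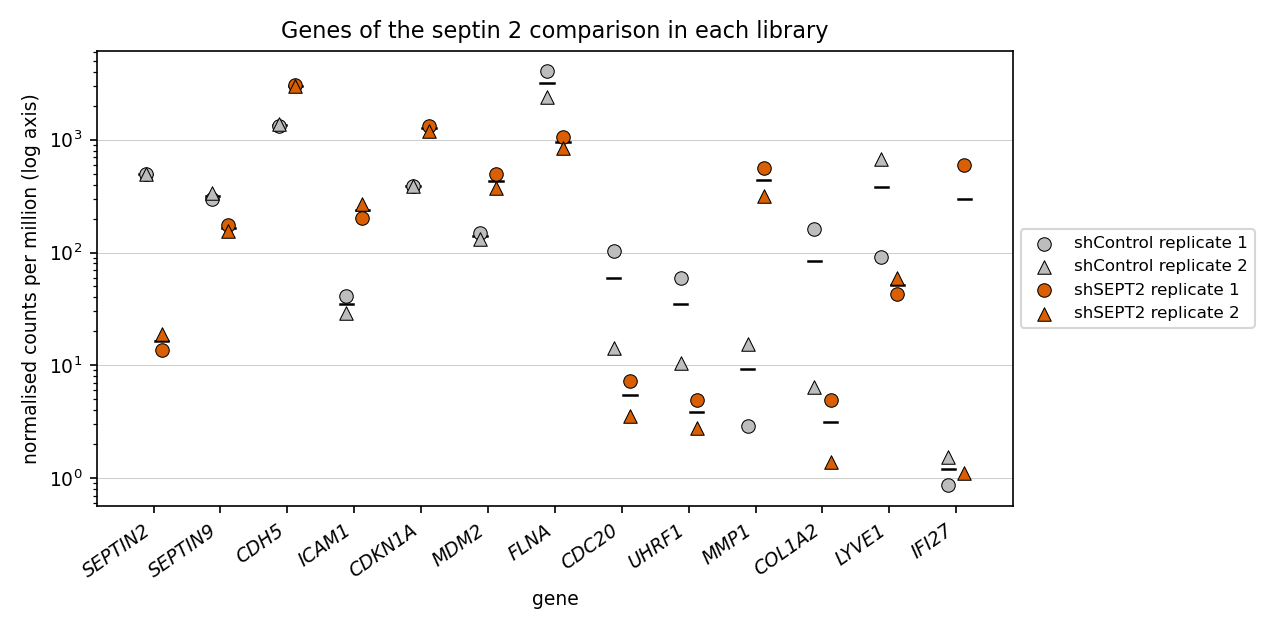
Normalised read counts (CPM) on a log axis for 13 genes of the septin 2 comparison, with each library as a point (circles replicate 1, triangles replicate 2) and the group mean as a bar. SEPTIN2 is near 492.6 CPM in both control libraries and at 13.5 and 19.0 CPM in the knockdown, while IFI27 is high in shSEPT2 replicate 1 alone, at 597.6 CPM.

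Camera without the block called none of the focal adhesion, matrix remodelling and actin and myosin lists (adjusted p = 0.124, 0.519 and 0.519). DESeq2 called 518 of 13685 genes over all, a share to set beside the list counts below. YAP and TAZ target genes rose as a list, with 5 of 19 members called by DESeq2 (6 adjusted over the list alone, 8 higher and 1 lower with the block over all genes), including ANKRD1, NUAK2, GADD45A and FJX1 at log2 fold changes of 1.90, 1.86, 1.46 and 1.38. At the estimated correlation (-0.05), a setting that also missed the simulated list, the YAP and TAZ list had a camera adjusted p of 0.743. Over the whole list, 4 members were called as higher without shControl replicate 1, when NUAK2 and GADD45A lost their calls, and 2 without shControl replicate 2, when GADD45A and FJX1 did. Without shSEPT2 replicate 1, 0 were called, and without shSEPT2 replicate 2, 0 as higher and 1 as lower. The integrin subunit ITGAV, the 1 called gene of 26 focal adhesion genes (4 rose and 2 fell with the block, 2 and 1 over the list alone), went from 220.4 ± 3.52 to 707.3 ± 165 CPM (SD, n = 2; log2 fold change 1.69), a call lost without shSEPT2 replicate 1 (adjusted p = 0.333) and shSEPT2 replicate 2 (0.0516). The collagenase gene MMP1 rose by 5.58 ± 0.81, and MMP10 by 2.84, of 21 matrix remodelling genes (3 rose and 2 fell over the list alone, 4 and 2 with the block), and the call of MMP10 was lost without shSEPT2 replicate 1 (adjusted p = 0.36). Among 33 actin and myosin genes FLNA, PXN and TPM4 fell, at -1.75, -1.03 and -0.89, and 0 rose (4 fell and 0 rose adjusted over the list alone, 4 and 1 with the block). The calls of PXN and TPM4 were lost whichever library was left out, and that of FLNA without shSEPT2 replicate 1 (adjusted p = 0.146) and shSEPT2 replicate 2 (0.323). FLNA, an actin crosslinker, was at 4029.7 and 2376.2 CPM in shControl and at 1047.1 and 844.5 CPM in shSEPT2. The arterial ligand EFNB2 fell by a log2 fold change of -1.41. Of 18 genes of the KLF2 and KLF4 programme and coagulation 2 rose, ASS1 by 2.90 and EDN1 by 1.47, and 1 fell, the prostaglandin synthase PTGS2, by -2.86 (2 and 1 over the list alone, 3 and 3 with the block). Of 23 chemokines and cytokines 3 rose, among them CCL2 by 2.08 and IL32 by 1.30, and 0 fell (4 and 1 over the list alone, 4 and 2 with the block). Without shSEPT2 replicate 2 the adjusted p was 0.171 for EFNB2, 0.101 for PTGS2, 0.622 for ASS1, 0.858 for EDN1, 0.868 for CCL2 and 0.302 for IL32. EFNB2, IL32 and EDN1 also lost their calls without shSEPT2 replicate 1 (0.72, 0.85 and 0.171) and shControl replicate 2 (0.135, 0.122 and 0.258), and CCL2 without shControl replicate 1 (0.165). Of 20 unfolded protein response genes 1 rose, ATF3 by 2.01 (2 over the list alone, 3 with the block), and of 20 cholesterol synthesis genes 1 rose, HMGCS1 by 1.17 (2 and 2), and 0 fell in both lists. Both calls were lost without either shSEPT2 library, that of ATF3 also without shControl replicate 1 (adjusted p = 0.0895) and that of HMGCS1 without shControl replicate 2 (0.274). Of 20 MHC class I genes and 21 TGF-beta and mesenchymal genes 0 were called (2 fell and 2 rose, respectively, with the block).

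Interferon-stimulated genes differed between the 2 shSEPT2 libraries. By DESeq2 5 of 33 were called as higher and 1 as lower (5 and 1 when adjusted over the list alone, 3 and 1 with the block), and RSAD2 was called below the low-count filter. The 1 lower gene was GBP2, named here after its value was seen, at -2.65 ± 0.43 SE (DESeq2 adjusted p = 5.36e-07, and 1.18e-06 with the block). IFI27 was at 597.6 CPM in shSEPT2 replicate 1 and at 1.12 CPM in shSEPT2 replicate 2, against 0.86 and 1.55 CPM in shControl. BST2 stood at 133.3 and 2.91 CPM, OAS2 at 134.4 and 4.66 CPM and MX2 at 18.6 and 0.10 CPM in the same 2 libraries. Without shSEPT2 replicate 1, 0 interferon genes were called as higher, 1 without shControl replicate 1, 2 without shControl replicate 2 and 13 without shSEPT2 replicate 2. The median of the list was 2.14 in pair 1 and -0.61 in pair 2. Its camera test gave an adjusted p of 0.114, and 0.0268 with the replicate block. With an estimated correlation its adjusted p was 0.783, without the block.

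Lymphatic markers had medians of -0.51 in pair 1 and -1.30 in pair 2, with 7 of 10 lower in both pairs and 1 higher in both. Fibroblast and mural cell markers had medians of -0.92 and -1.32, with 7 of 9 lower in both pairs and 0 higher in both. Camera called neither list without the block (adjusted p = 0.17 and 0.0789), and the adjusted p was 0.783 and 0.743 with an estimated correlation. LYVE1, a lymphatic endothelial receptor, was at 91.7 and 672.8 CPM in shControl and at 42.5 and 59.9 CPM in shSEPT2 (log2 fold change -2.89, adjusted p = 0.0313), and its adjusted p was 0.484 without shControl replicate 2, 0.349 without shSEPT2 replicate 1 and 0.123 without shSEPT2 replicate 2. Of the lymphatic markers 1 fell by DESeq2, LYVE1 (2 over the list alone, and 1 rose and 6 fell with the block). Of the fibroblast and mural cell markers 1 fell, COL1A2 (1 over the list alone, 2 with the block), and its call was lost without shControl replicate 1 (adjusted p = 0.815) and shSEPT2 replicate 2 (0.115). Without shControl replicate 1, 3 lymphatic markers were called as lower, 1 without shSEPT2 replicate 2, and 0 without shControl replicate 2 or shSEPT2 replicate 1. Of 7 leukocyte markers 0 were called by DESeq2 over all genes, 1 as higher when adjusted over the list alone and 1 as higher with the block. The 4 tested keratinocyte markers were too few for the list test, and 0 were called (1 as higher with the block).

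By the naming rule applied to DESeq2, 402 genes passed. The highest were BST2, LRRC38, MMP1, TAS1R1, PITX1, OAS2, SLC8A2, IFIT1, H2BC4, COL17A1, HDAC9 and CYGB, with log2 fold changes from 6.52 for BST2 to 3.69 for CYGB. Some of these sizes rest on few control reads. SLC8A2 had 3 and 55 reads in shControl replicates 1 and 2, PITX1 6 and 92, TAS1R1 9 and 301 and COL17A1 63 and 4. IFIT1 was at 40.3 and 0.68 CPM in shSEPT2 replicates 1 and 2, against 1.03 and 0.58 CPM in shControl. The lowest were HAPLN1, SEPTIN2, NEO1, COL1A2, SPOCD1, PARD6G, NTN1, ADAMTS15, NDRG4, CENPM, METTL7A and C1orf21, from -5.33 for HAPLN1 to -3.44 for C1orf21. With the replicate block 19 of the 24 were called, and BST2, OAS2, IFIT1, NEO1 and PARD6G were not. NEO1 and PARD6G stood at 92.6 and 118.6 CPM in shControl replicate 2 against 2.5 and 4.14 CPM in shControl replicate 1. Without shControl replicate 1, 7 of the 24 lost their calls (BST2, OAS2, IFIT1, HAPLN1, COL1A2, SPOCD1 and CENPM), and without shControl replicate 2, 7 did (BST2, OAS2, IFIT1, NEO1, PARD6G, NTN1 and ADAMTS15). Without shSEPT2 replicate 1, 11 did (BST2, TAS1R1, OAS2, SLC8A2, IFIT1, COL17A1, NEO1, PARD6G, NTN1, ADAMTS15 and CENPM), and without shSEPT2 replicate 2, 4 did (HAPLN1, COL1A2, NTN1 and CENPM).

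Whichever library was left out, 20 of the DESeq2 calls were kept, 13 higher and 7 lower. They include SEPTIN2, NDRG4 and METTL7A among the lower genes, and MMP1, LRRC38, HDAC9, APLN, PGK1 and ICAM1 among the higher. All of the kept calls were also made by DESeq2 with the block, and 15 by edgeR over all 8 libraries. Both fits reuse the septin 2 libraries on which these genes were selected, so they are no independent support. EdgeR on those 4 libraries called 0 genes with or without the block.

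The planned edgeR test called 0 of 13916 genes, with 1632 at an unadjusted p under 0.05, and edgeR with the block also called 0 (3136 unadjusted). DESeq2 called 518 (235 higher, 283 lower), DESeq2 with the block 1380, limma-voom 0 (1543 unadjusted), limma-voom with the block 102 and edgeR over all 8 libraries 336. In simulated data with independent genes 15.3% of the calls of DESeq2 with the block and 21.7% of those of limma-voom with the block were unchanged genes. Genes were named from DESeq2 only after these counts had been seen. The DESeq2 count was 68 without shSEPT2 replicate 1 and 165 without shSEPT2 replicate 2. The 2 shControl libraries differed by over 2-fold at 21.6% of genes, more than the libraries of pair 1 (18.5%) or pair 2 (16.9%).

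Camera called 4 of 25 lists in this comparison: p53 targets as higher (median log2 fold change 0.98, adjusted p = 2.66e-08), YAP and TAZ targets as higher (0.75, adjusted p = 0.00358), mitotic genes as lower (-2.72, adjusted p = 3.21e-08) and DNA replication genes as lower (-1.82, adjusted p = 8.06e-06). With an estimated correlation 0 lists were called: the adjusted p was 0.743 for the p53, YAP and TAZ and mitotic lists and 0.773 for DNA replication. That setting also missed the simulated mitotic list lowered by 1 (camera adjusted p = 0.997), so a call lost there does not show an unchanged list. Neither setting was tested on correlated genes. Fry called 0 lists. With the replicate block camera called 11, adding interferon genes, adherens junction (adjusted p = 0.0466), leukocyte adhesion (0.0268), focal adhesion (0.0467), septin-binding and cytokinesis genes (0.0466), lymphatic markers (0.0268) and fibroblast markers (0.00666). With an estimated correlation and no block these 7 lists had adjusted p values from 0.743 to 0.783. The adjusted p of the other 21 lists without the block lay between 0.0789 and 0.916, and of 24 NF-kB target genes 0 were called by DESeq2 over all genes or over the list alone, and 2 as higher with the block.

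**Figure D2:**
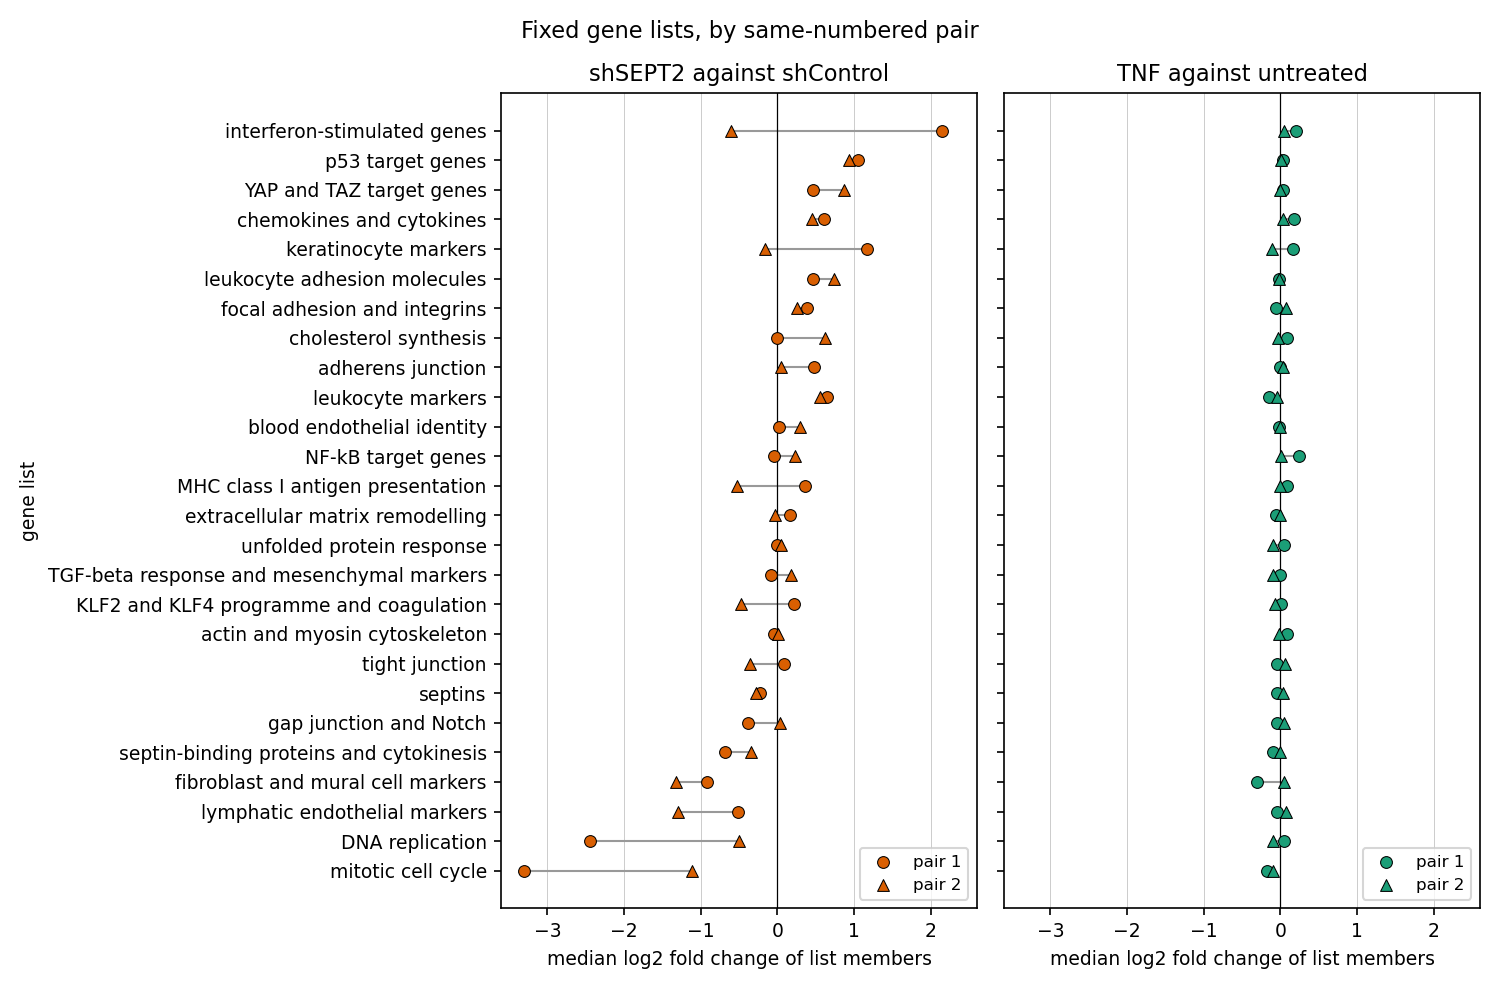
Median log2 fold change of the members of each of the 26 fixed lists, in the septin 2 comparison on the left and the TNF comparison on the right, with circles for pair 1, triangles for pair 2 and a line joining them. The p53 medians lie at 1.05 and 0.93 in the septin 2 pairs, the interferon medians at 2.14 and -0.61, and the mitotic medians in the TNF pairs at -0.17 and -0.09.

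The second comparison asked how TNF changes the transcripts of the same kind of cell. Genes that endothelial cells usually raise under TNF differed little between the libraries labelled TNF and the untreated ones. SELE, the endothelial selectin, was at 6.66 and 1.68 CPM in untreated cells and at 8.06 and 3.09 CPM in the libraries labelled TNF. VCAM1 was at 2.18 and 1.18 CPM against 3.08 and 1.58 CPM, and ICAM1 at 30.9 and 19.7 CPM against 44.4 and 24.1 CPM. NFKBIA, the inhibitor that NF-kB itself induces, was at 60.1 and 59.7 CPM against 68.6 and 56.4 CPM. TRAF1 had a log2 fold change of 0.88 (95% interval 0.41 to 1.36, adjusted p = 1 by edgeR; adjusted p = 0.0611 with the replicate block).

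NEAT1, the nuclear RNA that scaffolds paraspeckles, was the 1 gene called by DESeq2. It went from 152.4 ± 1.87 to 238.0 ± 12.02 CPM (SD, n = 2), a log2 fold change of 0.64 with an adjusted p of 0.0292 by DESeq2 and 0.000137 by edgeR with the replicate block. With that block edgeR called 7 genes, all higher and named here after their values were seen: NEAT1, MALAT1, MEG3, LENG8, SPTBN5, MAPK8IP3 and STAG3L5P-PVRIG2P-PILRB. MALAT1 had a log2 fold change of 0.54 in that fit, MEG3 of 0.55 and LENG8 of 0.46; LENG8, SPTBN5 and MAPK8IP3 are protein-coding. STAG3L5P-PVRIG2P-PILRB is a read-through transcript that shares sequence with its neighbours. SEPTIN2 was at 595.6 and 473.1 CPM in untreated cells and at 526.1 and 478.7 CPM in the libraries labelled TNF.

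Of 24 NF-kB target genes 0 were called by edgeR or DESeq2 over all genes or when adjusted over the list alone, 11 were higher in both pairs and 4 lower in both. The list's median log2 fold change was 0.13 (camera adjusted p = 0.245). Leukocyte adhesion molecules had a median of -0.02 (adjusted p = 0.903), chemokines and cytokines 0.15 (0.793) and interferon-stimulated genes 0.14 (0.0770). Camera called 1 of 25 lists, the mitotic genes, as lower (median -0.12, adjusted p = 0.00113; adjusted p = 0.952 with an estimated correlation), with 18 of 27 members lower in both pairs and 0 higher in both. That call was lost without untreated replicate 2 (adjusted p = 0.551) and without TNF replicate 1 (0.891).

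**Figure D3:**
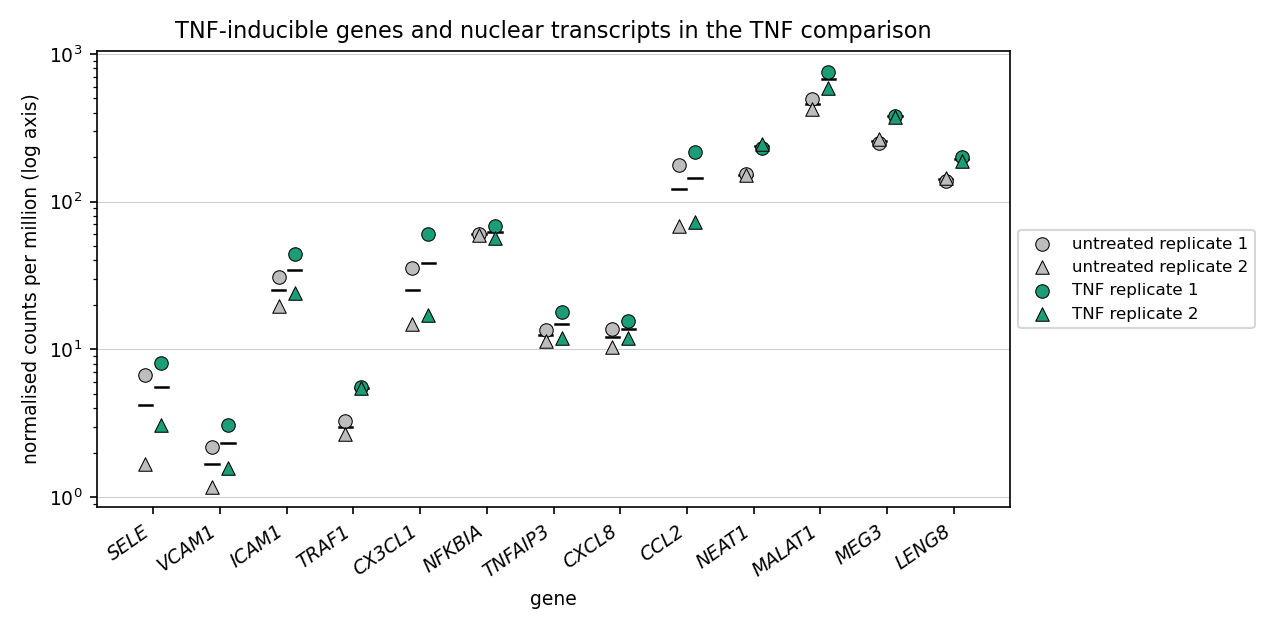
Normalised read counts (CPM) on a log axis for 9 TNF-inducible genes and 4 transcripts called with the replicate block, with each library as a point (circles replicate 1, triangles replicate 2) and the group mean as a bar. NEAT1 lies at 153.7 and 151.0 CPM in untreated cells and at 229.5 and 246.5 CPM in the libraries labelled TNF, while SELE differs more between replicates (6.66 and 1.68 CPM untreated) than between the labels.

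The planned edgeR test called 0 of 14045 genes, with 133 at an unadjusted p under 0.05. EdgeR with the block called 7, DESeq2 1, DESeq2 with the block 4, limma-voom 0 (133 unadjusted), limma-voom with the block 7, and edgeR over all 8 libraries 0 (27 unadjusted). Libraries of a pair differed by over 2-fold at 2.29% of genes in each pair, and the 2 untreated libraries at 4.68%.

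The 2 effects were compared across the 13603 genes tested in both. Their log2 fold changes correlated at a Pearson r of 0.047 and a Spearman rho of 0.027 across genes, which are not independent replicates. The septin 2 fold changes of the 2 pairs correlated with each other at 0.530, and those of TNF at 0.052. By edgeR 0 genes were called in both comparisons, since neither had calls, and 0 by DESeq2, whose calls would give 0.0172 genes higher in both by chance. A test of the difference of the 2 effects in 1 edgeR fit of the 8 libraries called SEPTIN2 alone (log2 difference -4.81 ± 0.31 SE, adjusted p = 0.0363; 1787 genes at an unadjusted p under 0.05), and 384 genes with the replicate block. Without any 1 shSEPT2, untreated or TNF library 0 genes were called in that test, 252 without shControl replicate 2 and 1 without shControl replicate 1, and DESeq2 called 360. The planned sets of genes raised or lowered by TNF, called at an absolute log2 fold change of at least 1, had no members. The 200 genes with the smallest p in each direction in the TNF comparison were taken instead, of which 190 and 181 were tested. They had median log2 fold changes of -0.16 and -0.05 in shSEPT2, and camera called neither set. Only 133 genes had an unadjusted p under 0.05 in the TNF comparison, so most members of these sets had no measured TNF effect. The sets therefore cannot show whether septin 2 suppression moves genes that respond to TNF.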

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

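Settings fixed before the data were examined left the count of changed genes at 0 in both comparisons under RLE scaling, both other filters, limma-voom, protein-coding genes alone and every omission of 1 library. The replicate block kept it at 0 for septin 2 and gave 7 for TNF. DESeq2 gave 518 and 1, and all 8 libraries in one fit 336 and 0. DESeq2 with the replicate block (1380 and 4) and limma-voom with it (102 and 7) were added after seeing the data. The cause was not tested, but the fit of 8 libraries shares its spread between the septin 2 libraries (biological coefficient of variation 42.3%) and the tighter TNF libraries (14.6%). The 518 DESeq2 calls became 1380 with the block, ranged from 68 to 598 without 1 library and were 487 at an absolute log2 fold change of at least 1, all added after seeing the data. Without shControl replicate 1, 226 of the 518 were shared, 234 without shControl replicate 2, 42 without shSEPT2 replicate 1 and 105 without shSEPT2 replicate 2.

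Splitting the same 4 septin 2 libraries by day gave 789 DESeq2 calls against 518 for the treatment and 0 for the crossed split. In the TNF libraries the day split gave 1916 by DESeq2 and 2520 by edgeR, against 1 and 0 for the treatment. The libraries are thus structured by replicate number, which goes with the day in the labels and with anything else in which the replicates differ. With the block the treatment gave 1380 calls by DESeq2 for septin 2 and 4 for TNF. With 3 splits of 4 libraries no share under 0.05 can be reached.

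The SEPTIN2 log2 fold change stayed between -5.18 and -4.68 without 1 library. It passed the threshold by DESeq2 (-4.92), by DESeq2 with the block (-4.93), by limma-voom with the block (-4.94) and in the fit of 8 libraries (-4.9), and not by edgeR with the replicate block (-4.94, adjusted p = 0.0648).

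Lists called in the septin 2 comparison went from 4 to 11 with the replicate block, to 0 with an estimated correlation, to 0 by fry, and to between 5 and 9 without 1 library (9 without shControl replicate 2). In the TNF comparison the count of 1 became 2 with no low-count filter, 2 at 10 CPM in 2 libraries, 0 with an estimated correlation, 0 by fry and 2 to 4 without 1 library (4 without TNF replicate 1, 3 without TNF replicate 2). The block left it at 1. Genes whose 2 effects differ went from 1 to 384 with the replicate block, 360 by DESeq2, 14 with no low-count filter and 0 to 252 without 1 library. The correlation of the 2 effects lay between -0.033 and 0.09 without 1 library. In the simulations camera with an estimated correlation missed a list of independent genes lowered by 1 that the preset correlation called. That setting can thus lose a call without correlated genes. The causes of these shifts were not otherwise tested.

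Signs turned for some genes without 1 library. Their edgeR log2 fold changes in the septin 2 comparison ranged from -0.23 to 5.65 for IFIT1, -0.10 to 8.96 for IFI27, -0.79 to 6.74 for MX2 and -0.25 to 0.13 for SEPTIN7. In the TNF comparison they ranged from -0.43 to 1.73 for SELE, -0.09 to 0.98 for VCAM1, -0.07 to 0.81 for ICAM1, -0.57 to 1.38 for CX3CL1, -0.09 to 0.20 for NFKBIA and -0.06 to 0.52 for TNFAIP3. They ranged from -0.22 to 0.80 for BIRC3, -0.01 to 0.42 for CXCL8, -0.75 to 1.07 for CCL2 and -0.25 to 0.09 for SEPTIN2. Of the other single-gene and list values, each counted once per setting, 1045 kept their direction and side of the threshold, 196 passed it only under the other setting and 12 no longer did. The base for genes was the planned edgeR test, which called 0, so no single gene could lose a call. These counts do not measure how stable the DESeq2 calls were. The sets of genes raised or lowered by TNF, which also required an absolute log2 fold change of at least 1, had no members under any setting, so no value is given beyond the 200-gene sets. What depth limits was not tested by drawing fewer reads.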

Other observations

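All tests below were chosen after the patterns they address had been seen, and only for those of the nuclear-retained list and of transcript length were the values they measure still unseen. Genes in the first 2 paragraphs were chosen after their values were seen. Of 31 replication-dependent histone genes, whose transcripts mostly lack poly(A) tails in cycling cells, 11 rose in shSEPT2 by DESeq2, 0 fell and 20 were not called, with 11 and 0 called with the replicate block. Their median log2 fold change was 1.24, and they were not tested as a group. H2AC6 was at 10.04 and 16.4 CPM in shControl and 100.1 and 57.4 CPM in shSEPT2, H2BC5 at 3.97 and 5.52 CPM against 35.9 and 31.8 CPM, and H2BC12 at 12.5 and 15.7 CPM against 80.6 and 39.6 CPM. Without shSEPT2 replicate 1 the calls of H2AC6 (adjusted p = 0.107) and H2BC12 (0.419) were lost.

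PGK1, a glycolytic kinase, rose 11.9-fold and 6.24-fold within the septin 2 pairs (DESeq2 log2 fold change 3.15 ± 0.40, adjusted p = 1.27e-11). CCND1 and CCND2, of the 3 D cyclin genes, rose: CCND1 was at 521.2 and 558.5 CPM in shControl and 1202.5 and 1340.0 CPM in shSEPT2, and CCND2 at 131.5 and 195.2 CPM against 609.6 and 883.7 CPM. CCND3 was at 165.2 and 84.4 CPM against 182.1 and 103.6 CPM and was not called. Without shSEPT2 replicate 2 the adjusted p was 0.582 for CCND1 and 0.102 for CCND2, and CCND1 also lost its call without shSEPT2 replicate 1 (0.447) and shControl replicate 1 (0.0747). Of 33 interferon-stimulated genes 26 were over 2-fold higher in shSEPT2 replicate 1 than in its paired control, and 4 in replicate 2, where 7 were over 2-fold lower.

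The libraries labelled TNF showed little of an endothelial TNF response. A spread or depth too large to see one is argued against for 4-fold changes: 0 of 24 NF-kB target genes had a 95% interval reaching a 4-fold rise in edgeR with the replicate block, and 1 without it. Labels swapped within 1 pair are argued against for a strong response, since the NF-kB medians were 0.24 in pair 1 and 0.01 in pair 2, 0.23 apart on the log2 scale. A response that had faded, a weak TNF stock and untreated cells under a TNF label cannot be told apart, because 1 dose and 1 time were measured. That 11 NF-kB genes were higher in both pairs and 4 lower in both, against 6 of each by chance for independent genes, leaves all of them open.

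Nuclear transcripts were higher in the libraries labelled TNF. A list of nuclear-retained and retained-intron transcripts, written without their values but after the pattern had been noticed in other genes, and without the 7 called ones, had medians of 0.21 and 0.23 in the pairs. Of its 37 tested members 32 were higher in both pairs and 0 lower in both (camera p = 1.71e-16 at the preset correlation and p = 0.0708 with an estimated one), so a larger nuclear or incompletely spliced share of the RNA is a candidate explanation. Transcript length is argued against, since 331 genes matched in exon length and level had a median of 0.00 against 0.54 for the called ones. An effect of TNF on these transcripts stays open. All 7 called ones were higher in both pairs, but they were selected as higher in these same libraries. Their agreement between the pairs therefore bears on neither explanation.

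Mitotic genes were lower and p53 targets higher in shSEPT2. The day in the labels as the whole cause is argued against by the design, since the libraries of a pair share it. Within those pairs 27 of 27 mitotic genes were lower in both. These genes moved together (estimated inter-gene correlation 0.97), so their agreement is close to 1 observation per pair. Differences between single cultures of the same day were not tested. Library scaling is argued against, since it shifts all genes alike, and the p53 and mitotic medians lay 4.35 and 2.06 apart in the pairs. Another effect of the hairpin or its virus cannot be told apart from the loss of septin 2 with 1 septin 2 hairpin group and 1 control group. The p53 median was 0.93 in pair 2, where the interferon median was -0.61, but that rests on 1 library.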
